A study of Mus musculus with 52 samples.

How the data were processed

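Gene expression was measured on Affymetrix arrays in mouse placentas and embryos collected 10.5 days after mating. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised, and the animals had a mixed 129SvEv, C57BL/6NTac and FVB/NTac background. The deposited values are on a log2 scale. The submitters' processing notes name RMA (background correction, quantile normalization and summary of the probes of a probe set), with no version, and no later step is given in the sources used here. The values of the 45101 probe sets ran from 1.64 to 14.95. There were 52 arrays, 26 per tissue, in 6 genotype groups per tissue, and no 2 arrays held identical values.

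Probe sets were named through the platform annotation supplied with the series. Of the 45101 probe sets, 34945 had 1 gene, 932 had several and 9160 were not named there, and 64 control probe sets were left out. The gene identifiers of 34741 named probe sets matched the supplied RefSeq gene table, and 204 did not and kept the name of the annotation. One probe set per gene, the one with the highest mean over all arrays, was tested, which gave 18193 genes. Of these, 9010 had several probe sets. Among genes with several probe sets called in the E2f7/E2f8 double knockout within array sets, 4 of 564 genes in the placenta and 75 of 1446 in the embryo had probe sets called in opposite directions. Probe sequences and the positions of probes within a gene were not used here.

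The designed comparisons, 17 in number, were fixed before the data were examined. Each was tested with limma 3.58.1 (lmFit and eBayes) under R 4.3.3 on the deposited log2 values, with 1 mean per genotype over all 26 arrays of a tissue, or over all 52 arrays for the difference between tissues. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called changed. This is called the fit over all arrays. Errors after ± are standard errors (SE) of the limma fit unless SD is written.

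The quantiles of the deposited columns (99 points per array) showed that RMA had not been run once over all arrays. The arrays were grouped by average linkage on the distance between their quantiles, with a limit of 0.5, which gave 6 array sets that were the same in placenta and embryo. The first held double knockouts 1 to 3 with wild types 1 and 2, the next triple knockouts 1 to 5 with wild types 3 and 4, and the next E2f3a knockouts 1 to 4 with wild types 5 and 6. Double knockout 4, the Cyp19Cre arrays and the Sox2Cre arrays each formed a set of their own without a wild type. A second fit, added after seeing the data, therefore compared each knockout only with the wild types of its own set (18 arrays per tissue, with the set as a block). It is called the fit within array sets. For the Cyp19Cre and Sox2Cre arrays the set and the genotype cannot be told apart within a tissue, so the placenta minus embryo difference of each set was compared with that of wild types 1 to 4, or of the other deletion. This difference, also added after seeing the data, removes a set effect that is the same in both tissues. As a check, wild types 1 and 2 were compared in this way with wild types 3 and 4, which are in another set: limma called 0 genes (803 at an unadjusted p under 0.05). The same comparison of wild types 5 and 6 with wild types 1 to 4 called 9043 genes (49.7%).

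The genes named in the text follow a rule fixed before the data were examined. It takes the targeted genes first; then, per comparison, the 10 largest increases and the 10 largest decreases of the fit over all arrays among called genes whose groups did not overlap, leaving out Xist, Y-linked and targeted genes; and, per gene list, up to 4 called members with the smallest adjusted p, or up to 2 where none was called. The rule was applied in the same way to the fit within array sets. For interactions and differences between tissues it used the adjusted p alone.

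The gene lists, 24 in number, were also fixed before the data were examined. They held the G1/S and E2F-responsive genes (29 of 30 listed genes measured), the DNA replication machinery (41 of 42), mitosis genes (31 of 32), DNA repair genes (25 of 28), p53 target and apoptosis genes (22 of 24), trophoblast giant cell markers (11 of 16), spongiotrophoblast and glycogen cell markers (26 of 27), labyrinth syncytiotrophoblast markers (16 of 19), trophoblast progenitor markers (18 of 18), maternal decidua markers (18 of 18), uterine natural killer cell markers (18 of 18), macrophage markers (16 of 16), endothelial markers (19 of 20), erythroid markers (21 of 24), adult globin genes (3 of 6), yolk sac and hepatic endoderm markers (19 of 22), hypoxia and glycolysis genes (30 of 34), integrated stress response genes (21 of 21), interferon response genes (19 of 22), neural progenitor and neuron markers (23 of 24), cardiac muscle markers (20 of 20), somite and skeletal muscle markers (19 of 20), imprinted genes (23 of 26) and Y-linked genes with Xist (4 of 5). Each list with at least 5 measured members, except the last, was tested with limma's camera (two-sided, preset inter-gene correlation 0.01, adjusted over the lists of a comparison), and again with an estimated correlation. Members past the threshold were counted over all genes tested and adjusted over the list alone.

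The procedure was tested on simulated arrays with 200 changed genes among 18193, 50 per size, for the double knockout comparison. At a true log2 change of 0.5 the fit over all arrays recovered 82% in the placenta and 86% in the embryo, and the fit within array sets 78% and 72%. At a change of 1 the shares were 100%, 100%, 90% and 100%. False calls made up 4.98%, 3.98%, 7.07% and 5.58% of the calls in the same order. The simulated arrays held no differences between array sets. The shares recovered and the false calls therefore leave out errors that such differences bring to the fit over all arrays. The number of arrays limits the precision: the fits within array sets rest on 2 wild types per set and tissue.

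Alternatives fixed before the data were examined were quantile normalization over the arrays of the fit, centring each array on its median, leaving out the genes below the median level, the mean of all probe sets of a gene, the arrays of the compared groups alone, trend and robust variances, array weights, the replicate number as a block, a minimum of 1.5-fold, the mean of the Y-linked genes as a covariate and leaving out each replicate in turn. The fits within array sets, the placenta minus embryo differences and the fit without wild types 5 and 6, with its list tests for Cyp19Cre and Sox2Cre, were added later. The labels do not say whether arrays of a group came from separate litters, so p-values measure the spread between these samples. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.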

Results

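Expression was measured in whole placentas and embryos of mice lacking members of the E2f family, transcription factors that control genes of the cell cycle. E2f7 and E2f8 are known as repressors of this family, and E2f3a, one product of the E2f3 gene, as an activator. In each tissue there were 6 wild types, 4 E2f3a knockouts, 4 E2f7/E2f8 double knockouts and 5 knockouts of all 3 genes (triple knockouts). There were also 3 samples in which E2f7 and E2f8 carried floxed alleles with Cyp19Cre, a Cre transgene of the trophoblast, and 4 with Sox2Cre, a Cre transgene of the epiblast, from which the embryo proper derives. The Sox2Cre animals carried 1 floxed and 1 deleted allele of each gene. Per the labels, deletions were checked by genotyping. The design addresses the loss of the repressors in placenta and embryo, its dependence on E2f3a, and deletion with each Cre.

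The median log2 value of an array ranged from 5.84 to 6.448 in the placenta and from 5.97 to 6.526 in the embryo, and it followed the array set more than the genotype. Wild types 1 and 2 shared a set with double knockouts 1 to 3, wild types 3 and 4 with the triple knockouts, and wild types 5 and 6 with the E2f3a knockouts. Between sets the medians lay apart: 6.177 to 6.203 in the placentas of the double knockout set, 6.372 to 6.392 in the E2f3a set and 6.424 to 6.448 in the triple knockout set. They were 6.136 to 6.143 for Sox2Cre and 5.84 to 5.882 for Cyp19Cre. The placentas of wild types 5 and 6 also stood apart in content. Set against wild types 1 to 4 and relative to their own embryos, their maternal decidua markers had a median log2 difference of 3.33 (15 of 18 higher). Their uterine natural killer cell markers had one of 3.06 (14 of 18 higher), and 38 of 41 replication genes were lower. Between wild types 1 and 2 and wild types 3 and 4, the placenta minus embryo difference passed in 0 genes with limma (803 at an unadjusted p under 0.05), but between wild types 5 and 6 and wild types 1 to 4 it passed in 9043 (49.7%). The fit over all arrays was set before the data were examined. The fit within array sets and the placenta minus embryo differences against wild types 1 to 4 were chosen after seeing these values, and counts of changed genes are given from the fit over all arrays and from one of these for each comparison. Other values come from the fit within array sets, or from these differences, unless stated.

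**Figure D1:**
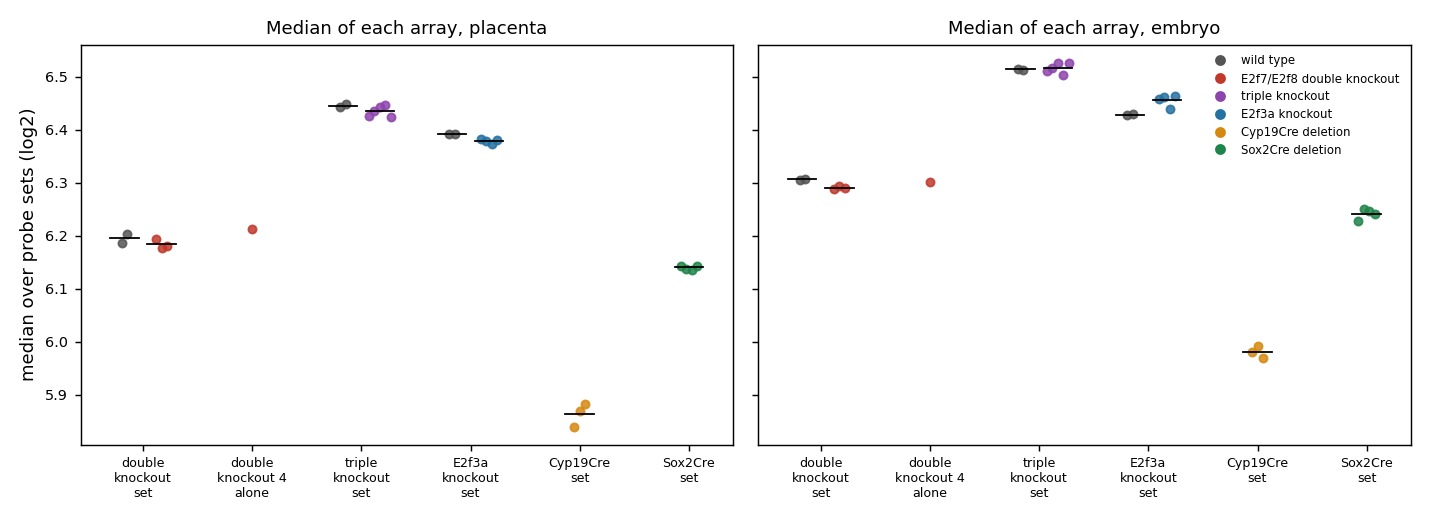
Median log2 value of each array (vertical axis) by array set (horizontal axis), in placenta and embryo; each point is 1 array, and wild types are marked apart. Wild types lie with the knockouts of their own set, and the 3 Cyp19Cre placentas, at 5.84 to 5.882, lie below all others.

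The targeted genes were read first. E2f7 had 1 probe set, and E2f8 and E2f3 had 2 each, which differed in brightness. Within array sets it was lower in double knockout placentas (9.25 ± 0.08 SD in the 3 double knockouts of the set against 10.97 ± 0.07 SD in wild types 1 and 2; log2 change -1.72 ± 0.13, adjusted p = 9.73e-07). It was also lower in their embryos (8.98 ± 0.14 SD against 10.28 ± 0.04 SD; -1.31 ± 0.11, adjusted p = 2.01e-06), and in triple knockout placentas (-1.49 ± 0.12) and embryos (-1.26 ± 0.10). It stood at 9.21 ± 0.05 SD in Cyp19Cre and 9.90 ± 0.46 SD in Sox2Cre placentas, and at 9.54 ± 0.17 SD and 9.06 ± 0.05 SD in the embryos. E2f3a knockouts had 8.67 ± 0.07 SD in the placenta, beside 8.71 ± 0.18 SD in wild types 5 and 6, and 8.86 ± 0.08 SD in the embryo, beside 9.49 ± 0.05 SD (-0.63 ± 0.10, adjusted p = 0.000996). Over all arrays E2f7 was not called in double knockout placentas (-0.87 ± 0.36, adjusted p = 0.0756), and it was at -0.92 ± 0.34 in triple (adjusted p = 0.0443) and -1.45 ± 0.36 in E2f3a knockout placentas (adjusted p = 0.00395). In the embryos of these groups it was at -1 ± 0.14, -1.09 ± 0.13 and -1.12 ± 0.14 over all arrays. With Cyp19Cre it was at -0.92 ± 0.39 in placentas (adjusted p = 0.0505) and -0.43 ± 0.15 in embryos, and with Sox2Cre at -0.23 ± 0.36 (adjusted p = 0.638) and -0.91 ± 0.14. The median gene of all lay at -0.347 in Cyp19Cre placentas and -0.345 in Cyp19Cre embryos, and at -0.0807 and -0.0793 with Sox2Cre. These shifts were not taken off the values of the targeted genes over all arrays, here or below. A Cyp19Cre value near the shift is therefore no sign of a lower targeted gene.

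Both probe sets of E2f8 were higher, not lower, in the double knockouts. The brighter one rose by 0.55 ± 0.09 in placentas (11.87 ± 0.04 SD against 11.32 ± 0.01 SD; adjusted p = 0.000972) and by 1.15 ± 0.15 in embryos (10.64 ± 0.37 SD against 9.49 ± 0.10 SD; adjusted p = 7.28e-05), and the dimmer one by 0.63 ± 0.13 and 0.99 ± 0.17. In triple knockouts the brighter one was at 11.84 ± 0.04 SD and 10.98 ± 0.11 SD (0.39 ± 0.08 and 1.30 ± 0.13 above wild types 3 and 4). The dimmer one was at 9.94 ± 0.14 SD and 9.10 ± 0.04 SD (0.30 ± 0.12, adjusted p = 0.151, and 1.34 ± 0.16). Cyp19Cre placentas and embryos had 11.59 ± 0.06 SD and 9.02 ± 0.24 SD on the brighter probe set, and 9.59 ± 0.04 SD and 6.61 ± 0.31 SD on the dimmer one. Sox2Cre placentas and embryos had 11.66 ± 0.05 SD and 11.13 ± 0.03 SD, and 9.61 ± 0.05 SD and 8.95 ± 0.12 SD. E2f3a knockouts had 10.09 ± 0.17 SD and 8.61 ± 0.05 SD, and 8.28 ± 0.19 SD and 6.99 ± 0.15 SD. Over all arrays the brighter probe set of E2f8 was at 0.93 ± 0.22, 0.91 ± 0.21 and -0.84 ± 0.22 in double, triple and E2f3a knockout placentas and at 1.26 ± 0.15, 1.63 ± 0.14 and -0.74 ± 0.15 in the embryos. It was at 0.66 ± 0.24 and -0.33 ± 0.17 (adjusted p = 0.0841) with Cyp19Cre, and at 0.72 ± 0.22 and 1.78 ± 0.15 with Sox2Cre. The dimmer one, over all arrays, was at 0.85 ± 0.22, 0.93 ± 0.20 and -0.73 ± 0.22 in the knockout placentas and at 0.78 ± 0.15, 1.67 ± 0.14 and -0.44 ± 0.15 in the embryos. It was at 0.58 ± 0.24 and -0.81 ± 0.16 with Cyp19Cre, and at 0.60 ± 0.22 and 1.52 ± 0.15 with Sox2Cre. The positions of the probes of all 3 genes relative to the deleted parts were not available here, so a probe set that did not fall checks no label.

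In E2f3a knockout embryos the brighter probe set of E2f3 was lower by -0.96 ± 0.07 (8.71 ± 0.05 SD against 9.67 ± 0.02 SD) and the dimmer one by -0.80 ± 0.11 (7.27 ± 0.16 SD). In triple knockout embryos they were lower by -0.85 ± 0.07 (9.83 ± 0.03 SD) and -0.75 ± 0.10 (7.52 ± 0.12 SD). In E2f3a knockout placentas the brighter one was lower (8.06 ± 0.09 SD, -0.31 ± 0.07, adjusted p = 0.0366). The dimmer one was at 7.25 ± 0.10 SD (0.00 ± 0.10). Triple knockout placentas had 9.89 ± 0.08 SD and 7.92 ± 0.11 SD, changes of -0.05 ± 0.07 and -0.21 ± 0.10. The 3 double knockout placentas of the set had 10.21 ± 0.06 SD and 8.16 ± 0.04 SD, increases of 0.35 ± 0.08 and 0.55 ± 0.11 within the set (adjusted p = 0.0117 and 0.00556). In triple against double knockout placentas, each against its own wild types, they were at -0.39 ± 0.11 (adjusted p = 0.1) and -0.75 ± 0.15 (adjusted p = 0.0238). Cyp19Cre placentas had 9.91 ± 0.06 SD and 7.65 ± 0.13 SD, and Sox2Cre placentas 9.86 ± 0.04 SD and 8.11 ± 0.10 SD. The embryos of these groups, with all 4 double knockouts, had 10.55 ± 0.33 SD and 7.99 ± 0.10 SD, 10.17 ± 0.14 SD and 7.38 ± 0.06 SD, and 10.68 ± 0.10 SD and 8.54 ± 0.06 SD. Over all arrays the brighter and the dimmer probe set of E2f3 were at -1.33 ± 0.25 and -0.41 ± 0.15 in E2f3a knockout placentas (adjusted p = 0.00173 and 0.0249), and at -1.59 ± 0.17 and -0.85 ± 0.09 in the embryos. Triple knockout placentas had the opposite sign over all arrays, 0.50 ± 0.23 and 0.25 ± 0.14 (adjusted p = 0.097 and 0.151), and the embryos had -0.47 ± 0.16 and -0.60 ± 0.08. Double knockouts had 0.82 ± 0.25 and 0.44 ± 0.15 in placentas, and 0.25 ± 0.17 and -0.13 ± 0.09 in embryos (adjusted p = 0.259 and 0.268). With Cyp19Cre the values were 0.52 ± 0.27 and -0.01 ± 0.16 in placentas (adjusted p = 0.107 and 0.968), and -0.13 ± 0.19 (adjusted p = 0.574) and -0.74 ± 0.10 in embryos. With Sox2Cre they were 0.47 ± 0.25 (adjusted p = 0.149) and 0.45 ± 0.15 in placentas, and 0.38 ± 0.17 (adjusted p = 0.11) and 0.42 ± 0.09 in embryos. Over all 6 wild types, E2f7, the E2f8 probe sets and the E2f3 probe sets had 10.12 ± 1.12, 10.93 ± 0.71, 9.01 ± 0.66, 9.39 ± 0.79 and 7.66 ± 0.42 SD in placentas. They had 9.97 ± 0.40, 9.35 ± 0.39, 7.43 ± 0.26, 10.30 ± 0.49 and 8.12 ± 0.15 SD in embryos.

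Double knockout placentas had more RNA of nearly the whole cell cycle programme than wild types 1 and 2. Of the DNA replication machinery, 40 of 41 measured genes rose (median log2 change 0.68), with Mcm4 at 1.10 ± 0.05 (12.45 ± 0.03 SD in 3 double knockouts against 11.35 ± 0.06 SD in 2 wild types, adjusted p = 1.33e-08) and Mcm6 at 1.17 ± 0.06, both parts of the replicative helicase. The G1/S and E2F-responsive list had 26 of 29 members higher (median 0.56), among them the checkpoint kinase Chek1 at 1.48 ± 0.07 (adjusted p = 1.55e-08) and the uracil-DNA glycosylase Ung at 1.24 ± 0.07. Of the mitosis genes 28 of 31 rose (median 0.51), with Prc1 at 0.75 ± 0.06. Of the DNA repair genes 15 of 25 rose (median 0.48), with Brca1 at 0.79 ± 0.06. No member of these 4 lists fell. Hypoxia and glycolysis genes moved with them, 18 of 30 higher and 2 lower (median 0.39), led by the oxygen sensor Egln1 at 0.91 ± 0.09 and the mitophagy receptor Bnip3 at 1.10 ± 0.12. Adjusted over the list alone the counts were 41 of 41, 28 of 29, 30 of 31, 19 of 25 and 24 of 30 higher (3 lower). All 5 shifts passed camera (adjusted p from 6.91e-54 to 3.31e-13) and held with an estimated correlation (adjusted p from 0.000492 to 0.00404).

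Among single genes of the double knockout placenta, the largest increases over all arrays that also passed within array sets were Fbxo2 (2.42 ± 0.27 within sets, adjusted p = 2.76e-05), the replication factors Gins2 (1.86 ± 0.12) and Mcm10 (1.18 ± 0.07), and the adenylate kinase Ak4 (1.73 ± 0.16). They also included Psrc1 (1.33 ± 0.15), Pop4 (1.53 ± 0.07), Pfpl (1.99 ± 0.56) and the trophoblast transcription factor Elf5 (0.98 ± 0.24). The decreases included the placental hormone gene Prl8a1 (-2.85 ± 0.53, adjusted p = 0.00265), the pregnancy-specific glycoprotein genes Psg18 (-2.76 ± 0.61) and Psg28 (-2.46 ± 0.53), Ceacam14 (-2.15 ± 0.47), Igfbp7 (-1.56 ± 0.28), Ccdc141 (-1.39 ± 0.21) and Emp1 (-1.13 ± 0.22). The spongiotrophoblast and glycogen cell list, to which several of these belong, had 6 of 26 members lower and none higher (median -0.62, 7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000419, 0.487 with an estimated correlation). Endothelial markers had 5 of 19 lower, with Plvap at -0.82 ± 0.14 and the TGF-beta co-receptor Eng at -0.56 ± 0.12 (median -0.36, 10 lower adjusted over the list alone; adjusted p = 2.08e-06, 0.32 with an estimated correlation).

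Of the further lists in double knockout placentas, uterine natural killer cell markers moved about as far as the endothelial markers. Giant cell markers had 3 of 11 lower (median -0.13, adjusted p = 0.0583). The p53 target and apoptosis genes 5 of 22 higher (median 0.13, adjusted p = 0.0359, 0.393 with an estimated correlation), and trophoblast progenitor markers 3 higher and 4 lower of 18. Uterine natural killer cell markers had 2 of 18 lower (median -0.37, 9 lower adjusted over the list alone, adjusted p = 0.00166, 0.471 with an estimated correlation). Erythroid markers had 2 of 21 lower (-0.26), macrophage markers 1 of 16 (Csf1r, the receptor of a macrophage growth factor, at -1.66 ± 0.19) and labyrinth markers 2 of 16. Maternal decidua markers had 1 higher and 1 lower of 18 (median -0.06, adjusted p = 0.393), but a median of -0.28 and adjusted p = 0.00714 without wild type 1, and 0.16 and 0.451 without wild type 2. In all, 2101 genes changed within array sets (1049 higher, 1052 lower), 681 without wild type 1 and 1285 without wild type 2. Over all arrays 3713 changed (1516 higher, 2197 lower; 2627 and 1514 after renewed quantile normalization), but 103 with only the arrays of both groups in the fit. Of the 3713, 1231 passed within array sets in the same direction and none in the opposite one.

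Double knockout embryos showed a different picture, led by hypoxia and glycolysis genes. Of this list 28 of 30 members rose, by a median log2 change of 1.48 (28 also adjusted over the list alone), with Bnip3 at 2.06 ± 0.18 (adjusted p = 4.37e-06), the glucose transporter Slc2a3 at 1.65 ± 0.16 and the glycolytic enzyme Tpi1 at 0.95 ± 0.09. With an estimated correlation the list had adjusted p = 0.0944. Integrated stress response genes rose in 17 of 21 cases (median 0.89, 18 adjusted over the list alone), with Stc2 at 4.05 ± 0.38 and Vldlr at 2.19 ± 0.25 (for the list, adjusted p = 0.19 with an estimated correlation). Neural progenitor and neuron markers fell in 16 of 23 cases and rose in 1 (median -0.69, the same counts adjusted over the list alone), with the neuronal RNA-binding protein Elavl3 at -1.15 ± 0.09 and the neurofilament gene Ina at -1.13 ± 0.11 (for the list, adjusted p = 0.0566 with an estimated correlation). The preset camera test passed for all 3 (adjusted p = 2e-26, 9.24e-12 and 1.31e-10). Replication genes rose less often than in the placenta, 23 of 41 (median 0.26), as did G1/S genes, 14 of 29 (0.22, with Ung at 1.11 ± 0.08), and mitosis genes had 2 higher and 3 lower of 31 (-0.04, adjusted p = 0.251; -0.09 and 0.0332 without double knockout 1). With an estimated correlation the replication and G1/S lists had adjusted p = 0.19 each. The tests of these differences follow.

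Among the largest increases in double knockout embryos were Stc2, the immediate early gene Ier3 (3.28 ± 0.30, adjusted p = 5.1e-06), the vasodilator peptide gene Adm (3.27 ± 0.36), the hypoxia-responsive Bhlhe40 (3.30 ± 0.33) and Ankrd37 (2.52 ± 0.32), the glycolytic genes Eno2 (3.17 ± 0.45) and Pfkp (2.72 ± 0.28), and Ppp1r3c (2.54 ± 0.30). Among the decreases were Lamp5 (-2.17 ± 0.28), C1qtnf3 (-2.01 ± 0.18), the glutamate transporter Slc17a6 (-1.62 ± 0.23) and the neuronal factor Nhlh2 (-1.31 ± 0.14). Others were Agtr2 (-1.31 ± 0.21) and the sterol regulator Insig1 (-1.08 ± 0.11). DNA repair genes had 12 higher and 2 lower of 25 (median 0.20), endothelial markers 11 higher and 1 lower of 19 (0.33) and cardiac muscle markers 7 of 20 higher (0.35), with the natriuretic peptide gene Nppb at 2.68 ± 0.22. None of these 3 held with an estimated correlation (adjusted p = 0.19, 0.19 and 0.375). Somite and skeletal muscle markers had 2 higher and 5 lower of 19 (-0.03), and none of the 3 adult globin genes passed. Within array sets 4242 genes changed (2013 higher, 2229 lower), 2176 without wild type 1 and 2195 without wild type 2. Over all arrays 4977 changed (1606 higher, 3371 lower; 2813 and 2737 after renewed quantile normalization), and 853 with only the arrays of both groups. Both fits called 2339 in the same direction.

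The difference between the tissues was tested directly, as the double knockout effect in the placenta minus that in the embryo. Proliferation genes responded more in the placenta: 28 of 31 mitosis genes (median difference 0.52, 29 adjusted over the list alone), 27 of 41 replication genes (0.39, 37) and 18 of 29 G1/S genes (0.39, 18) had a higher effect there. Kif20a, a mitotic kinesin, was at 0.96 ± 0.10, Prc1 at 0.79 ± 0.08 and Mcm6 at 0.66 ± 0.08. In the embryo the effect was higher for 19 of 30 hypoxia genes (-0.82), 15 of 21 stress response genes (-0.94) and 14 of 19 endothelial markers (-0.72). Examples were Ndrg1 at -2.48 ± 0.37, Vldlr at -2.08 ± 0.33 and Eng at -0.89 ± 0.16. Bhlhe40 (-3.74 ± 0.46) and Adm (-2.66 ± 0.58) led toward the embryo, and Fbxo2 (2.23 ± 0.44) and Elf5 (1.73 ± 0.33) toward the placenta. Camera passed for all 6 lists. With an estimated correlation the mitosis, G1/S, replication and endothelial shifts held (adjusted p = 0.00311, 0.0201, 0.0275 and 0.0371), and the hypoxia and stress response shifts did not (0.0538 and 0.0584). Within array sets 2372 genes differed (1290 higher, 1082 lower), 1261 without placenta of wild type 1 and 1440 and 1424 without embryo of wild type 1 or 2. The count was 1931 over all arrays (1105 higher, 826 lower; 1853 and 1062 after renewed quantile normalization), 155 with only the arrays of these groups and 4780 with embryo and placenta of 1 number as a block.

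**Figure D2:**
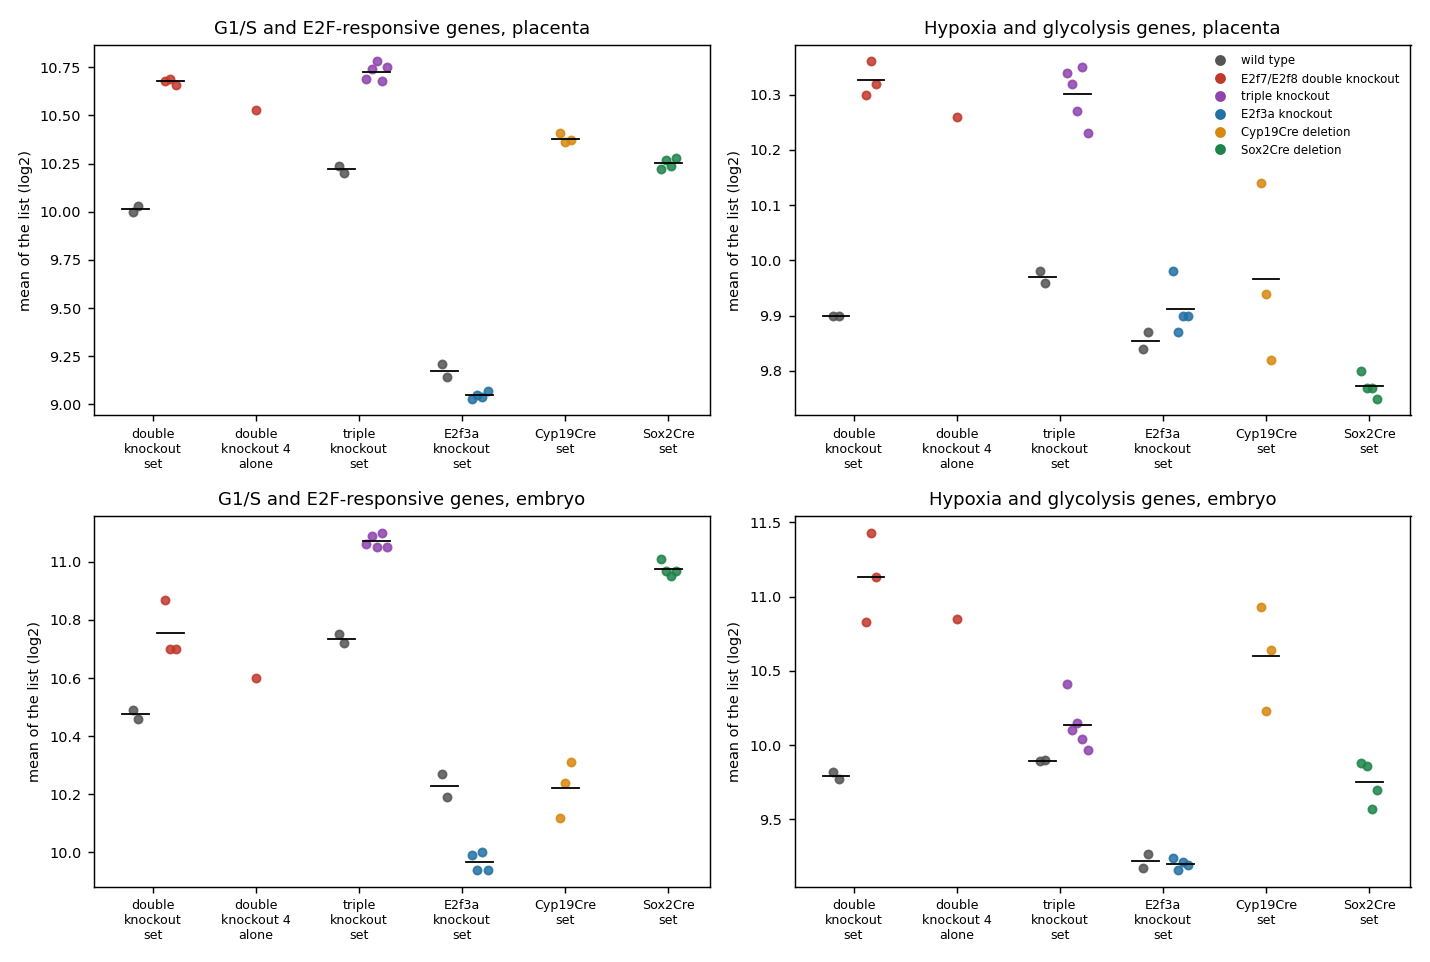
Mean log2 value per array (vertical axes) of the G1/S and E2F-responsive genes and of the hypoxia and glycolysis genes, by array set, in placenta and embryo; points are arrays and bars group means. Within its set, the G1/S mean of the double knockouts lies above that of the wild types in the placenta, and the hypoxia mean does so in the embryo.

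Loss of E2f3a on top of E2f7 and E2f8 left the cell cycle genes of the placenta high. Against wild types 3 and 4, triple knockout placentas had 36 of 41 replication genes higher (median 0.54, 39 adjusted over the list alone), 25 of 29 G1/S genes higher and 1 lower (0.50, 26 and 1), 20 of 31 mitosis genes higher (0.30, 24) and 12 of 25 repair genes higher (0.30, 14). Chek1 was at 1.26 ± 0.07 and Mcm4 at 0.95 ± 0.05. Hypoxia genes had 15 higher and 3 lower of 30 (0.30). p53 target genes had 11 of 22 higher (0.25), with the cyclin kinase inhibitor Cdkn1a at 1.48 ± 0.12 and the death gene Pmaip1 at 1.71 ± 0.20, and interferon response genes 9 of 19 (0.32). Maternal decidua markers rose too, 12 of 18 (median 1.01, 13 higher and 1 lower adjusted over the list alone), with A2m at 3.57 ± 0.39, Des at 1.65 ± 0.17, Hoxa10 at 1.30 ± 0.14 and the progesterone receptor Pgr at 1.16 ± 0.15, while 0 of 18 uterine natural killer cell markers passed (0.04). Apart from the natural killer markers, these 8 lists passed camera and held with an estimated correlation (adjusted p = 0.00381, 0.00152, 0.0202, 0.0202, 0.00951, 0.0202, 0.0397 and 0.0339 in the order named). Spongiotrophoblast markers had 8 lower and 1 higher of 26 (-0.46, or -0.25 without wild type 3 and -0.27 without triple knockout 3) and erythroid markers 4 of 21 lower (-0.45), neither held with an estimated correlation (adjusted p = 0.399 and 0.31).

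Large changes of the triple knockout placenta included increases of Fbxo2 (2.88 ± 0.24, adjusted p = 2.24e-06), Rinl (2.10 ± 0.15), Trim34a (2.02 ± 0.14), the guanylate-binding protein gene Gbp2b (1.94 ± 0.42), the cardiac myosin gene Myh6 (1.93 ± 0.27), Sult1e1 (1.88 ± 0.21), the keratin gene Krt14 (1.78 ± 0.31) and Gins2 (1.59 ± 0.11). Decreases included Gdpd3 (-3.18 ± 0.33), Ceacam13 (-2.43 ± 0.64), Prl2b1 (-1.74 ± 0.45), Ttc30b (-1.67 ± 0.25) and Chd9 (-1.28 ± 0.16). In all, 2145 genes changed (1310 higher, 835 lower), 978 without wild type 3 and 775 without wild type 4. Over all arrays 5424 changed (4755 higher, 669 lower; 2084 and 1955 after renewed quantile normalization), and 349 with only the arrays of both groups. Both fits called 1082 in the same direction. Of the genes changed within array sets, 495 were higher in both the double and the triple knockout placenta (76 for independent lists) and 357 lower in both (48), with 21 opposite.

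The direct comparison of triple with double knockout placentas, each against its own wild types, called few genes. No G1/S, replication, mitosis or repair gene passed (medians -0.16, -0.14, -0.21 and -0.20), and although camera passed for the first 3 lists (adjusted p = 1.68e-05, 5.03e-05 and 5.46e-08), it did not with an estimated correlation (0.231, 0.412 and 0.231). The decidua list had 6 of 18 members higher (median 0.87, 12 adjusted over the list alone; adjusted p = 9.46e-14, 0.0943 with an estimated correlation). Gatm (3.43 ± 0.37), the mesothelial gene Msln (3.26 ± 0.19, adjusted p = 3.65e-07), the oxidase gene Nox4 (3.17 ± 0.33) and Slpi (2.61 ± 0.24) were higher, and Gdpd3 (-3.49 ± 0.48) and Ipp (-2.40 ± 0.49) lower. Within array sets 266 genes differed (221 higher, 45 lower), 147, 116, 124 and 50 without wild type 1, 2, 3 or 4. Over all arrays, where the sets were not allowed for and the median gene lay 0.205 higher, 5792 differed (5308 higher, 484 lower; 1610 and 2099 after renewed quantile normalization), and 10055 with only the arrays of both groups.

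In triple knockout embryos the hypoxia, stress response and neural changes of the double knockout were mostly not seen, while the replication genes stayed up. Against wild types 3 and 4, 24 of 41 replication genes (median 0.36, 30 higher and 1 lower adjusted over the list alone) and 13 of 29 G1/S genes (0.27, 16) rose, with Ung at 1.17 ± 0.07, the activator E2f1 at 1.02 ± 0.09 and Mcm10 at 0.89 ± 0.07. Both lists held with an estimated correlation (adjusted p = 0.0153 for each). Hypoxia genes had 2 of 30 higher (Pdk1, which limits pyruvate oxidation, at 1.22 ± 0.24, and Higd1a at 0.44 ± 0.09, or -0.12 as the mean of its probe sets; median 0.17), stress response genes 0 of 21 (-0.06) and neural markers 1 of 23 (-0.08). Against the double knockout embryos, 23 of 30 hypoxia genes (median -1.10, 26 adjusted over the list alone) and 13 of 21 stress response genes (-0.95, 16) were lower and 11 of 23 neural markers higher (0.69, 12). Camera passed for these 3 lists (adjusted p = 8.84e-22, 1.38e-13 and 6.62e-10), and with an estimated correlation it did not (adjusted p = 0.157, 0.281 and 0.0695). Stc2 was at -4.42 ± 0.52, Adm at -3.16 ± 0.49 and Ina at 1.69 ± 0.15, and 1 G1/S gene and no replication gene passed.

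Single genes of this contrast included Ier3 (-3.19 ± 0.41), Bhlhe40 (-3.15 ± 0.44), Slc7a3 (-3.14 ± 0.47) and Chac1 (-2.88 ± 0.69), lower in triple than in double knockout embryos, and Rmst (1.82 ± 0.18), Sspn (1.31 ± 0.17) and Insig1 (0.93 ± 0.15), higher. Rmst, a long non-coding RNA of the nervous system, was also higher than in wild type (2.01 ± 0.12), and Ttc30b was lower (-1.80 ± 0.20). Triple knockout embryos differed from wild type in 334 genes (175 higher, 159 lower), 101 without wild type 3 and 90 without wild type 4, and from double knockouts in 1292 (538 higher, 754 lower). The latter count was 2717 without double knockout 1, 848 without double knockout 2, and 651, 404, 628 and 287 without wild type 1, 2, 3 or 4. Over all arrays the counts were 4628 (4292 higher, 336 lower; 1523 and 1229 after renewed quantile normalization) and 9220 (8037 higher, 1183 lower; 3612 and 3395), with median gene shifts of 0.179 and 0.26. With only the arrays of both groups, 252 genes differed from wild type.

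**Figure D3:**
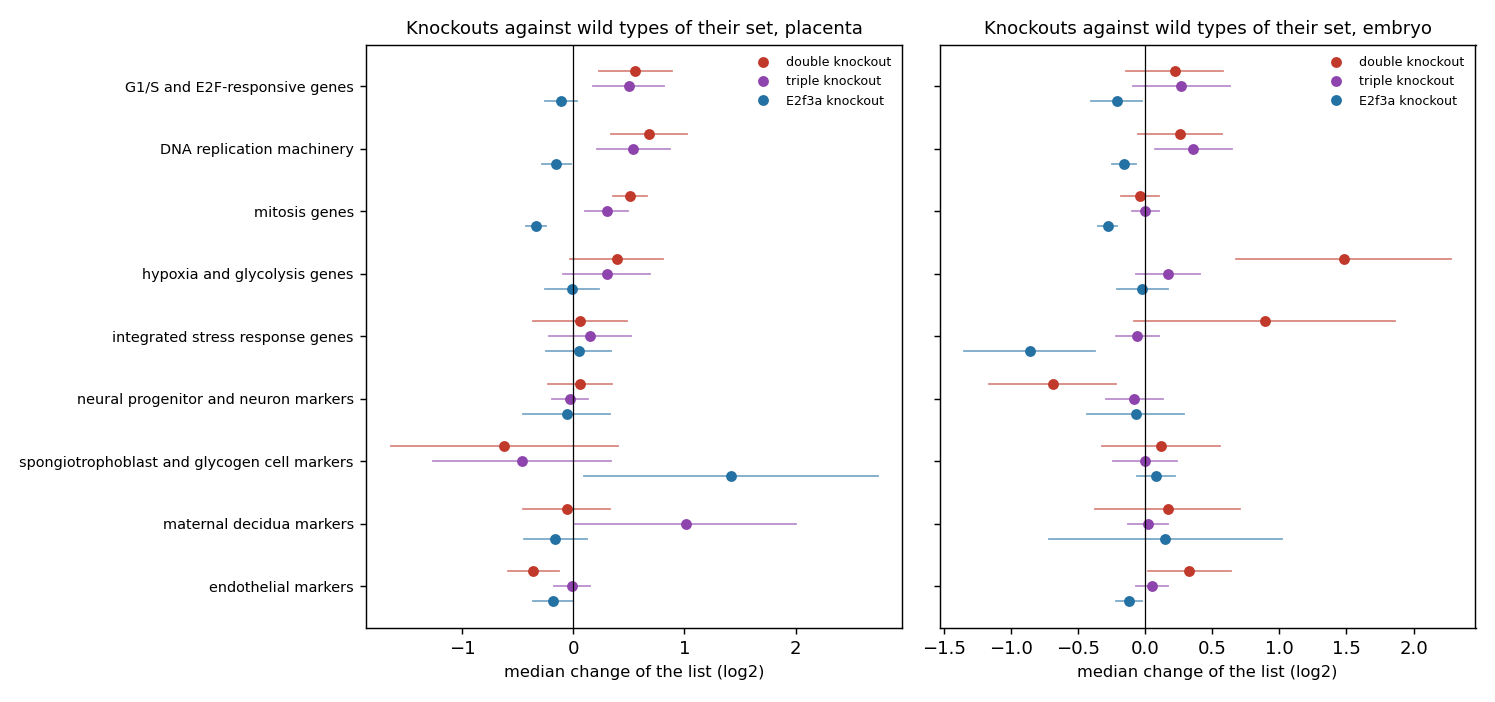
Median log2 change within array sets (horizontal axis, bars SD over the members of a list) of 9 gene lists in the double, triple and E2f3a knockouts, in placenta and embryo. The replication list lies at 0.68 and 0.54 in double and triple knockout placentas and at -0.15 in E2f3a knockout placentas, and the hypoxia list at 1.48 and 0.17 in double and triple knockout embryos.

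E2f3a knockout placentas had slightly less mitotic RNA than wild types 5 and 6, and many of their spongiotrophoblast markers were higher. Of the spongiotrophoblast and glycogen cell markers 13 of 26 rose (median 1.42, 19 adjusted over the list alone), led by Ceacam12 (4.60 ± 0.27, adjusted p = 5.67e-07), Prl8a8 (4.18 ± 0.26) and Prl8a6 (2.99 ± 0.28), though with an estimated correlation the list had adjusted p = 0.0521. Ceacam14 (4.65 ± 0.45) and the protease gene Ctsm (3.91 ± 0.29) were among the largest changes of all genes. Labyrinth markers had 5 of 16 higher (0.28, 8 higher and 1 lower adjusted over the list alone) and imprinted genes 6 of 23 (0.23, 9), with the growth factor gene Igf2 at 0.40 ± 0.09 (for these lists, adjusted p = 0.14 and 0.12 with an estimated correlation). Of the mitosis genes 21 of 31 fell (-0.33, 28), with Prc1 at -0.47 ± 0.06, and this list held with an estimated correlation (adjusted p = 0.0342). So did 9 of 41 replication genes (-0.15, 16) and 5 of 29 G1/S genes (-0.11, 7), with Cdc6 at -0.47 ± 0.07, but these lists did not hold (adjusted p = 0.14 and 0.12 with an estimated correlation).

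The placental lists of other cell types were flat or slightly lower in the E2f3a knockout within its set, with decidua markers 2 of 18 lower (-0.16, or -0.10 without E2f3a knockout 4) and uterine natural killer markers 3 of 18 lower, among them the granzyme gene Gzma at -1.30 ± 0.13 (median 0.02, while camera was negative, adjusted p = 0.0332, 0.526 with an estimated correlation). Over all arrays, with wild types 1 to 4 included, the same lists were 14 of 18 higher each (medians 2.09 and 2.26), and all 41 replication genes lower (-1.04). The E2f3a knockout placentas were thus rich in these markers themselves, as were wild types 5 and 6. A link between the share of maternal tissue and the higher spongiotrophoblast markers within the set was not tested. Of the largest changes over all arrays, Ceacam14, Ceacam12, Ctsm, Prl8a8, Ceacam9 (-1.29 ± 0.28) and the chromatin protein gene Hmga2 (-1.08 ± 0.20) passed within the set, and Fgl2 (0.81 ± 0.22), Coch (1.28 ± 0.49), Aqp1 (0.50 ± 0.41) and Star (-0.57 ± 0.30) did not. Within array sets 791 genes changed (432 higher, 359 lower), 329 without wild type 5 and 101 without wild type 6. Over all arrays 9342 changed (2569 higher, 6773 lower; 3585 and 5726 after renewed quantile normalization), but 24 with only the arrays of both groups in the fit. Of the 9342, 262 passed within array sets in the same direction and 169 in the opposite one.

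E2f3a knockout embryos had lower RNA of mitosis and DNA repair genes than wild types 5 and 6. Mitosis genes fell in 22 of 31 cases (median -0.28, 30 adjusted over the list alone), with the spindle factor Tpx2 at -0.44 ± 0.07, and repair genes in 8 of 25 (-0.22, 14). Both lists held with an estimated correlation (adjusted p = 0.0498 for each). G1/S genes fell in 11 of 29 cases (-0.21, 19), with the cyclin gene Ccne2 at -0.94 ± 0.11, and replication genes in 10 of 41 (-0.16, 18), but these lists did not hold (adjusted p = 0.113 and 0.222 with an estimated correlation). Stress response genes fell in 15 of 21 cases (-0.86, 17), with the asparagine synthetase Asns at -1.74 ± 0.17 and the serine pathway enzymes Psat1 at -1.23 ± 0.14 and Shmt2 at -1.29 ± 0.12. Cardiac markers fell in 11 of 20 (-0.62, 16), with Myl7 at -1.11 ± 0.18. With an estimated correlation these lists had adjusted p = 0.153 each. The pluripotency and early embryo genes Lin28a (-1.99 ± 0.20, adjusted p = 1.87e-05), Trim71 (-1.14 ± 0.14) and Sall4 (-1.12 ± 0.12) were lower. So were Igdcc3 (-1.59 ± 0.17), Prtg (-1.42 ± 0.16), Zbtb16 (-1.02 ± 0.09) and Hoxb1 (-0.92 ± 0.14). Alb, the liver albumin gene (2.06 ± 0.33), Penk (1.96 ± 0.24), Egfl6 (1.90 ± 0.14), Ogn (1.75 ± 0.17), Agtr2 (1.74 ± 0.20) and the muscle factor Myod1 (1.32 ± 0.20) were higher. Yolk sac and hepatic endoderm markers had 9 of 19 higher and 2 lower (0.97, 11 and 2; adjusted p = 0.321 with an estimated correlation).

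In E2f3a knockout embryos 1677 genes changed within array sets (928 higher, 749 lower), 485 without wild type 5 and 861 without wild type 6. Over all arrays 8183 changed (2083 higher, 6100 lower; 3383 and 4316 after renewed quantile normalization), and 4104 with only the arrays of both groups. Both fits called 1288 in the same direction.

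The interaction asked whether E2f3a loss acted differently with and without E2f7 and E2f8. In the embryo it was negative for 15 of 30 hypoxia genes (median -0.89, 23 adjusted over the list alone) and positive for 9 of 23 neural markers (0.60, 12) and 7 of 31 mitosis genes (0.30, 19). With an estimated correlation these lists did not hold (adjusted p = 0.21, 0.101 and 0.21). Eno2 was at -3.95 ± 0.74, Ier3 at -3.44 ± 0.50 and Lin28a at 1.33 ± 0.35. In the placenta it was positive for 5 of 18 decidua markers (1.05, 12) and negative for 5 of 26 spongiotrophoblast markers (-1.29, 10). Neither list held by that test (adjusted p = 0.067 and 0.25). Ceacam12 was at -4.19 ± 0.47, Gdpd3 at -3.72 ± 0.59 and Endou at 2.30 ± 0.43. All 5 lists passed camera at the preset correlation. The interaction was called in 852 embryo genes (336 positive, 516 negative), 2431 without double knockout 1, 517 without double knockout 2, and 454, 217, 232, 300, 280 and 437 without wild type 1 to 6 in turn. In the placenta it was called in 237 (173 positive, 64 negative), 157 without double knockout 2, and 154, 105, 112, 81, 155 and 75 without wild type 1 to 6. Over all arrays the counts were 10321 (9135 positive, 1186 negative; 4212 and 3434 after renewed quantile normalization) and 8579 (7835, 744; 2833 and 2185). Both fits called 573 embryo genes and 58 placenta genes in the same direction.

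To ask how genes chosen in the double knockout respond to E2f3a loss, genes were chosen with 2 of the 4 double knockouts and measured in the triple knockout against the other pair, over the 6 splits. Genes higher in the double knockout placenta lay -0.10 ± 0.02 (SD over splits) lower in the triple knockout and genes that were lower lay 0.41 ± 0.05 higher. In the embryo the values were -0.28 ± 0.10 and 0.52 ± 0.07. These carry the set difference. Within array sets the genes were chosen anew, with 2 of the 3 double knockouts and 1 of the 2 wild types of the set, over 6 splits, and measured in the left-out double knockout minus the left-out wild type and in the triple knockout minus wild types 3 and 4. In the placenta they had 0.38 ± 0.06 in the triple knockout against 0.52 ± 0.10 in the left-out double knockout when higher, and -0.22 ± 0.01 against -0.45 ± 0.07 when lower. In the embryo they had 0.04 ± 0.02 against 0.42 ± 0.14, and -0.09 ± 0.01 against -0.42 ± 0.15.

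Across genes, which are not independent replicates, the effects of the double and triple knockout correlated at r = 0.60 in the placenta (covariance 0.101) and 0.17 in the embryo (0.015) over all arrays. Simulated unchanged groups that shared simulated wild types gave 0.43 in both tissues (covariance 0.0166 and 0.00816, 20 simulations). These simulated wild types held no differences between array sets. The value of 0.43 is therefore no reference for the measured wild types, which lie in different sets. With different wild types as controls of each knockout, the measured effects correlated at 0.31 and 0.03. Within array sets, which share no wild types, r was 0.46 and 0.28. The double knockout and Cyp19Cre effects correlated at 0.84 in placentas (0.59 with split wild types) and 0.71 in embryos (0.53). The double knockout and Sox2Cre effects did so at 0.77 (0.50) and 0.47 (0.30), the Cyp19Cre and Sox2Cre effects at 0.80 (0.55) and 0.60 (0.40), and the double knockout and E2f3a knockout effects at -0.78 (-0.69) and -0.42 (-0.42). Within array sets the last pair had r = -0.24 in placentas and -0.19 in embryos. The correlations over all arrays carry differences between array sets, which splitting the wild types does not remove. Pairs with Cyp19Cre or Sox2Cre have no value within array sets. Their correlations therefore cannot tell a like effect of the genotypes from a like difference of the sets.

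With deletion of E2f7 and E2f8 by Cyp19Cre the cell cycle genes were higher in the placenta relative to the embryo. In the placenta minus embryo difference against wild types 1 to 4, 39 of 41 replication genes (median 0.68, 39 adjusted over the list alone), 25 of 29 G1/S genes (0.60, 26 higher and 1 lower), 21 of 31 mitosis genes (0.35, 22) and 15 of 25 repair genes were higher, with 1 repair gene lower (0.42, 16 and 1). Endothelial markers were lower in 15 of 19 cases (-0.86, 17) and p53 target genes higher in 8 of 22 and lower in 1 (0.21). These 6 lists held with an estimated correlation (adjusted p = 0.000264, 0.000125, 0.0192, 0.00471, 0.0192 and 0.0192), and the hypoxia genes, 20 of 30 lower (-0.66, 22), did not (0.0783). Within tissues the hypoxia list did not lie below the median gene. Against wild types 1 to 4 it lay 0.49 above it in placentas (8 higher, 7 lower) and 1.17 in embryos (22 higher, 2 lower). Fbxo2 (3.62 ± 0.37, adjusted p = 3.51e-09), Pfpl (2.82 ± 0.51), Slco5a1 (2.77 ± 0.27), Myh6 (2.27 ± 0.41) and Pmaip1 (2.00 ± 0.28) were among the highest, and Psg28 (-2.97 ± 0.47), Ceacam11 (-2.80 ± 0.88), Bhlhe40 (-2.75 ± 0.38) and Aldh1a3 (-2.34 ± 0.34) among the lowest. The difference was called in 3149 genes (1580 higher, 1569 lower), and in 6658 when wild types 5 and 6 were included.

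Within each tissue the Cyp19Cre set could not be separated from the genotype, and the median gene lay -0.347 lower than wild type in the placenta and -0.345 in the embryo. Relative to that shift, replication genes were 1.08 higher in placentas (29 of 41 higher before the shift was taken off) and G1/S genes 0.96 (15 of 29 higher, 1 lower), with adjusted p = 0.116 and 0.0946 with an estimated correlation. Against wild types 1 to 4 alone, a fit added after seeing the data, the shift was -0.419 and the values relative to it were 0.66 (27 higher, 2 lower) and 0.65 (16 higher, 2 lower), with adjusted p = 0.00012 and 0.000764 with an estimated correlation. Before the shift was taken off the medians were 0.24 and 0.23. Camera compares a list with the other genes, so its p-values here include the shift. Mitosis genes passed too (camera adjusted p = 0.047 with an estimated correlation), with a median of 0.02 before the shift was taken off (6 higher, 7 lower of 31). In embryos replication and G1/S genes lay 0.16 and 0.09 above the shift, and 0.01 and 0.02 against wild types 1 to 4. Hypoxia genes of the Cyp19Cre embryos were 1.36 higher relative to the shift (24 of 30 higher and 1 lower, adjusted p = 9.31e-53, 0.00879 with an estimated correlation), with Stc2 at 2.84 ± 0.39, Ier3 at 2.64 ± 0.27, Bhlhe40 at 2.51 ± 0.30 and Adm at 2.46 ± 0.35. In the placentas Fbxo2 (3.49 ± 0.35), Pfpl (2.87 ± 0.50) and Myh6 (2.25 ± 0.33) were among the highest and Ceacam13 (-3.74 ± 0.66) and Psg28 (-3.60 ± 0.39) among the lowest. The counts were 9441 in the placenta (414 higher, 9027 lower) and 10084 in the embryo (202 higher, 9882 lower). After renewed quantile normalization they were 3860 (2343 and 1517) and 2599 (1311 and 1288), and with only the arrays of both groups 3196 and 5755.

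Deletion with Sox2Cre gave the reverse in the placenta minus embryo difference: 14 of 41 replication genes (median -0.21, 19 adjusted over the list alone) and 8 of 29 G1/S genes (-0.14, 10) had the higher value in the embryo. No mitosis gene passed (0.05). Both shifts held with an estimated correlation (adjusted p = 0.00579 for each). Pkmyt1, a kinase that restrains mitotic entry (-0.89 ± 0.07, adjusted p = 7.29e-12), and Ung (-1.07 ± 0.10) led toward the embryo, and A2m (2.52 ± 0.59) and Scgb1a1 (1.95 ± 0.34) toward the placenta. In all 69 genes were called (14 higher, 55 lower), 34 and 38 without placenta of wild type 2 or 3, and 43, 41 and 35 without embryo of wild type 1, 3 or 4. The number was 4622 with wild types 5 and 6. Sox2Cre placentas too carried 1 deleted allele of each gene. Within tissues, relative to shifts of all genes of -0.0807 and -0.0793, replication genes were 0.68 higher in placentas (19 of 41 higher) and 0.71 in embryos (34 of 41), and G1/S genes 0.64 (11 of 29) and 0.46 (19 of 29). None of these held with an estimated correlation (adjusted p = 0.621, 0.142, 0.621 and 0.0712). Wild types 5 and 6 enlarge these values: against wild types 1 to 4 alone, relative to shifts of -0.143 and -0.148, replication genes were 0.29 higher in placentas (16 of 41) and 0.48 in embryos (24 of 41), and G1/S genes 0.28 (9 of 29) and 0.40 (13 of 29). These 4 held with an estimated correlation (adjusted p = 0.0173, 0.0147, 0.0364 and 0.00457). Their medians before the shift was taken off were 0.14, 0.33, 0.14 and 0.25. The embryos had Ndufs5 (2.16 ± 0.16), Mid1 (2.02 ± 0.45), Pkmyt1 (1.45 ± 0.18), Ung (1.39 ± 0.13), E2f2 (1.23 ± 0.18) and E2f1 (1.23 ± 0.15) among the highest. Macrophage markers were lower in 11 of 16 cases in both tissues (adjusted p = 0.621 and 0.33 with an estimated correlation), with Ctss among the largest decreases (-2.53 ± 0.65 and -1.81 ± 0.30; -1.21 and -1.37 against wild types 1 to 4). The counts were 3622 (359 higher, 3263 lower; 1074 and 677 after renewed quantile normalization) and 3716 (387 and 3329; 1050 and 912), and 14 and 771 with only the arrays of both groups.

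Cyp19Cre against Sox2Cre in the placenta minus embryo difference needs no wild type. Replication genes (39 of 41, median 0.88, 40 adjusted over the list alone), G1/S genes (26 of 29, 0.76, 27) and mitosis genes (20 of 31, 0.33, 22) were higher, and all held with an estimated correlation (adjusted p = 1.03e-05, 3.25e-06 and 0.0201). Gins2 (2.30 ± 0.13, adjusted p = 7.26e-17), Ung (2.09 ± 0.10) and E2f2 (2.03 ± 0.15) were among the highest and Ceacam11 (-3.76 ± 0.88) and Psg28 (-3.16 ± 0.47) among the lowest, with 2643 genes called (1231 higher, 1412 lower). Within tissues the shifts of all genes were -0.255 and -0.258. In embryos 38 of 41 replication genes and 26 of 29 G1/S genes were lower with Cyp19Cre (-0.53 and -0.45 relative to the shift, adjusted p = 0.324 and 0.218 with an estimated correlation) and 18 of 30 hypoxia genes higher and 1 lower (0.97, 0.0201). In placentas 14 of 26 spongiotrophoblast markers were lower (-0.76, 0.547) and 6 hypoxia genes higher and 3 lower (0.46, 0.00777). Counts were 3588 in placentas (133 higher, 3455 lower; 546 and 461 after renewed quantile normalization) and 5151 in embryos (198, 4953; 698 and 791), and 10008 and 9840 with only the arrays of both groups.

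**Figure D4:**
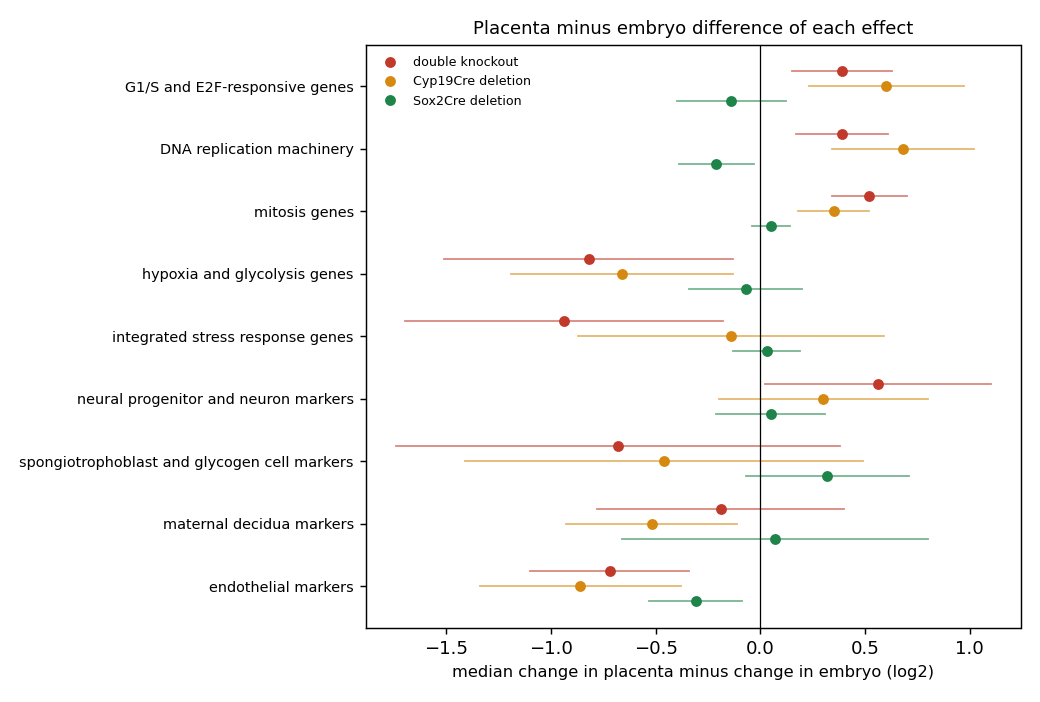
Median placenta minus embryo difference in log2 change (horizontal axis, bars SD over the members of a list) of 9 gene lists for the double knockout, Cyp19Cre and Sox2Cre. The replication list lies at 0.39, 0.68 and -0.21 in this order.

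The Y-linked genes of the list separated the arrays, 33 between 2.61 and 5.47 on average and 19 between 6.22 and 8.53. The mix differed between groups. E2f3a knockout placentas had 0 of 4 arrays with high Y-linked genes beside 2 of 2 for wild types 5 and 6, and E2f3a knockout embryos 1 of 4 beside 2 of 2. The triple knockouts had 3 of 5 beside 0 of 2 in each tissue, double knockouts of the first set 2 of 3 beside 1 of 2, Cyp19Cre 1 of 3 and Sox2Cre 0 of 4. Placentas of wild types 5 and 6 also had Xist at 11.87 and 12.09, where other placentas with high Y-linked genes had 7.70 to 9.35. With the mean of the Y-linked genes as a covariate, each of the 31 counts stayed within 1.5 times. In the placentas of the E2f3a set, high Y-linked genes and genotype coincided. The covariate could not tell them apart there.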

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

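The tests of a single array, of the E2f3a knockout genes in triple against double knockout embryos, of the uterine natural killer cell markers and of the posterior Hox genes below were chosen after the results were seen, as were the fit within array sets and the placenta minus embryo differences against wild types 1 to 4. The bound for the E2f3a knockout genes was also changed after its value was seen. The double knockout effect differed between placenta and embryo in 1931 genes over all arrays and in 2372 within array sets, by a test of the difference itself. Within array sets the tissue difference had a median log2 value of 0.39 for G1/S genes, 0.39 for replication genes, 0.52 for mitosis genes, 0.28 for DNA repair genes and -0.72 for endothelial markers. The interaction of E2f3a with E2f7 and E2f8 was called in 8579 genes of the placenta over all arrays and 237 within array sets. Only 58 passed in both fits in the same direction, and the effects of the 2 fits correlated at 0.00371 across genes. In the embryo 10321 and 852 genes were called, with 573 in the same direction and a correlation of 0.614.

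In 4 of 130 tested sets of list means and target gene levels within a group, 1 array stood apart, where chance gives about 1 in 20. Triple knockout embryo 2 had a mean log2 of 7.97 for the decidua markers (others 7.33 to 7.51). E2f3a knockout embryo 4 had 8.04 for the decidua markers (7.18 to 7.26) and 5.26 for the spongiotrophoblast markers (4.58 to 4.65). Double knockout embryo 1 had 4.58 for the spongiotrophoblast markers (4.5 to 4.51). Of 10092 probe sets with no single gene name, which entered no comparison by gene, 186 (1.84%) changed within array sets in double knockout placentas and 624 (6.18%) in double knockout embryos.

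Decidua markers were higher in triple knockout placentas than in wild types 3 and 4, by a median of 1.01. A single array is argued against, since the lowest median with 1 array left out was 0.93. Maternal tissue of the makeup seen in wild types 5 and 6 is argued against too: uterine natural killer cell markers, which rose there with the decidua markers (3.06 beside 3.33), had a median of 0.04 in the triple knockout (0 of 18 passed). Maternal tissue of another makeup stays open, since 100 other genes high in wild types 5 and 6 had a median of 0.66 in the triple knockout (51 higher, camera p = 2.14e-27, 0.00131 with an estimated correlation), against 0.04 in the double and -0.19 in the E2f3a knockout, each within its set. The 100 genes were chosen with the wild types that also served as controls. That favours higher values in the triple and double knockouts and lower ones in the E2f3a knockout. Whether the decidua markers rose through dissection or through the genotype was not tested.

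In E2f3a knockout embryos 1677 genes differed from wild types 5 and 6, among them Lin28a, Trim71 and Sall4, which were lower, and Alb and Myod1, which were higher. Knockout embryos further in development than these wild types may account for part of it: the posterior Hox genes, which embryos switch on later and which were chosen as a list after the results were seen, had a median of 0.71 (12 of 14 higher, camera p = 2.88e-19, 0.000106 with an estimated correlation). Yolk sac tissue left on the embryos stays open for the yolk sac genes, with a median of 0.51 for 5 visceral endoderm genes, of which 1 passed (Dab2; camera p = 0.0341, 0.295 with an estimated correlation). An effect of E2f3a loss that does not depend on E2f7 and E2f8 has values against it but stays open: the 1677 genes had a signed median of 0.40 in the E2f3a knockout, 0.08 in triple against double knockout embryos, each against its own wild types (upper quartile 0.30, SD over genes 0.36, 63.3% in the same direction), 0.01 in the triple knockout against wild type (SD 0.18, 53.2%) and -0.07 in the double knockout (SD 0.38). The bound set first, on the upper quartile, excluded this effect, and the bound on the SD that replaced it after the 0.08 was seen does not, while an effect that needs E2f7 and E2f8 was not tested apart from stage.

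Genes near the targeted loci that changed alike in placenta and embryo were counted, since DNA of another strain could be carried along with a knockout allele. Near E2f7 and E2f8, 11 of 200 measured neighbours (5.5%) changed alike in the double knockout against 3.26% of other genes (1-sided Fisher's exact test, p = 0.0661), and near E2f3 2 of 100 (2%) against 0.498% in the E2f3a knockout (p = 0.0912). By the same exact test, the shares in the triple knockout were 1% near E2f7 and E2f8 (2 of 200) against 0.923% (p = 0.554) and 3% near E2f3 (3 of 100) against 0.912% (p = 0.0654), and at the loci not targeted they were 1.5% near E2f7 and E2f8 in the E2f3a knockout (3 of 200) against 0.495% (p = 0.0809) and 3% near E2f3 in the double knockout (3 of 100) against 3.28% (p = 0.642). The bound written beforehand, which took any p of 0.05 or more as evidence against carried DNA, was wrong, since the first 2 shares were above those of other genes and a p that misses the threshold excludes nothing. Carried DNA cannot be told apart from other causes for these genes with so few changed neighbours.

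For each count of changed genes between 2 groups over all arrays, the arrays were regrouped into groups of the same sizes. As many genes were called in 14 of 100 splits for the double knockout placenta (3713, highest other 8489), 11 of 100 for the E2f3a knockout placenta (9342, 13420; 24 with only these arrays in the fit) and 14 of 100 for Sox2Cre placentas (3622, 8020), so chance is not excluded there over all arrays. Chance was excluded, at 1 of 100 splits, for triple against double knockout placentas (5792, 2837) and embryos (9220, 5859), triple knockout placentas (5424, 4379) and embryos (4628, 3224) and Sox2Cre embryos (3716, 3353). It was also excluded for double knockout embryos at 4 of 100 (4977, 6560), E2f3a knockout embryos at 2 of 100 (8183, 11623), Cyp19Cre placentas at 4 of 84 (9441, 9655), Cyp19Cre embryos at 1 of 84 (10084, 9853), and Cyp19Cre against Sox2Cre at 1 of 35 in placentas (3588, 694) and embryos (5151, 519). For the interactions and the tissue difference the residuals of a model without the tested term were permuted instead, in 100 arrangements with the real one among them. As many genes were called in 1 of 100 for the interaction in placenta (8579, 7998) and embryo (10321, 5226), where chance was excluded, and in 18 of 100 for the tissue difference (1931, 8103), where it was not. Splits that call more genes than the real one point to a structure of the samples, whose nature this did not test; within array sets the double knockout and E2f3a counts were 2101 and 791 in placentas and 4242 and 1677 in embryos. Excluding chance does not exclude the array sets, and regrouping mixed arrays of different sets. With embryos and placentas of 1 number taken as pairs, a fit that calls fewer genes, chance was excluded at 1 of 35 splits each for Cyp19Cre (2435, 360), Sox2Cre (46, 1) and Cyp19Cre against Sox2Cre (2053, 902).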

How the results depend on the processing

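The fits within array sets, the placenta minus embryo fits and the exclusion of wild types 5 and 6, list tests included, were chosen after seeing the data. Of the alternatives listed beforehand, 6324 of 6675 values of named genes, 263 of 360 counts and 190 of 200 list tests kept their direction and side of the threshold (counts: within 1.5 times), and of those added 2343 of 2494, 179 of 240 and 300 of 304. The list tests cover the G1/S list alone over all arrays and 8 of the 24 lists within array sets, there with 1 array left out. The totals leave out the estimated correlation of other lists and their tests for Cyp19Cre and Sox2Cre without wild types 5 and 6. All 31 counts stayed within 1.5 times with trend and robust eBayes, with the mean of all probe sets and with the Y-gene covariate. The cause of the changes below was not tested, except that fewer genes or arrays enter where a setting leaves some out. Signal over background was not analysed here, and the number of arrays, with 2 wild types in each set, limits the precision.

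Within array sets the interaction of Cxcl14 (0.51), Mgp (0.35), Penk (0.74) and Prss23 (0.06) in the placenta and of Rbm45 (-0.24) in the embryo changed sign, as did Prcc in triple against double knockout embryos (-0.23). With the mean of all probe sets Xaf1 changed sign in triple knockout placentas against double knockouts (1.15) and wild types (0.67), and Higd1a in triple knockout embryos (-0.12).

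Within array sets the placental counts were 2101 (double knockout), 2145 (triple), 266 (triple against double), 791 (E2f3a) and 237 (interaction). Those of the embryo were 334 (triple), 1292 (triple against double), 1677 (E2f3a) and 852 (interaction). Placenta minus embryo, they were 3149 for Cyp19Cre, 69 for Sox2Cre and 2643 for Cyp19Cre against Sox2Cre. After renewed quantile normalization the counts that moved were, in placentas, 3860 (Cyp19Cre), 1751 (Sox2Cre), 1007 (Cyp19Cre against Sox2Cre), 3709 (triple against double) and 5018 (interaction). They were 2599, 1962 and 1489 in embryos for the same Cre comparisons, 2752 (triple) in embryos, and 2915 for the tissue difference. With median centring they were, in placentas, 4684 (Cyp19Cre), 766 (Cyp19Cre against Sox2Cre), 2655 (triple), 3861 (triple against double) and 3213 (interaction). In embryos they were 3647, 1361 and 2333 for the first 3.

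Without the genes below the median level the counts were, in placentas, 2384 (double), 2945 (triple), 1312 (triple against double), 3394 (Cyp19Cre), 517 (Sox2Cre), 2203 (Cyp19Cre against Sox2Cre) and 4748 (interaction). In embryos they were, in the same order, 2551, 1004, 3349, 3367, 642, 2671 and 5660. At 1.5-fold or more they were 1538, 1602, 2567, 4888, 1425 and 1273 in placentas for the first 6, with 4885 for E2f3a. In embryos they were 1355, 780, 3628, 3921, 954 and 1474, with 2777 for E2f3a. With only the arrays of the groups compared they were 103, 349, 10055, 3196, 14 and 10008 in placentas, with 24 for E2f3a. In embryos they were 853 (double), 252 (triple), 5755 (Cyp19Cre), 771 (Sox2Cre), 9840 (Cyp19Cre against Sox2Cre) and 4104 (E2f3a), and 155 for the tissue difference. With array weights they were, in placentas, 1875 (double), 11595 (triple against double), 1825 (Sox2Cre), 11287 (Cyp19Cre against Sox2Cre) and 13096 (interaction). In embryos they were 2767 (double), 1879 (Sox2Cre) and 10875 (Cyp19Cre against Sox2Cre). Without wild types 5 and 6 they were 2826 (triple knockout embryos) and 13479 (interaction in placentas).

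Replicate numbers did not pair samples of different genotypes: 12 of 52 same-numbered pairs of placentas and 5 of 52 of embryos correlated above 0.1. Of the embryos and placentas of 1 genotype and number, 10 of 25 pairs did, but 25 of 26 were alike in the Y-linked genes (16.3 by chance, one-sided exact permutation test within genotypes, p = 0.000278, the smallest these groups allow). That is a hint from the data that most came from 1 conceptus, which the labels do not say. With the replicate number as a block the counts were 4780 for the tissue difference over all arrays (2569 within array sets, beside 2372), 1604 for double knockout placentas and 2130 for Sox2Cre placentas, and the other 18 counts stayed within 1.5 times.

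With an estimated correlation the G1/S list over all arrays lost its call in placentas of the double knockout (median 0.86, adjusted p = 0.257), triple knockout (1, 0.417), E2f3a knockout (-0.9, 0.514), Cyp19Cre (0.61, 0.0946) and Sox2Cre (0.56, 0.621). It lost it in embryos of the double (0.19, 0.345), triple (0.45, 0.554) and E2f3a knockout (-0.6, 0.481) and Sox2Cre (0.38, 0.0712). Of the responses to E2f3a loss, genes higher in the double knockout placenta had -0.14 without a split and -0.14 within array sets, and lower ones 0.53 and 0.23. In embryos higher ones had -0.44 at an adjusted p under 0.01 and lower ones 0.32 within array sets.

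With 1 array left out, where a lone remaining wild type is assumed to vary like the other groups, counts over all arrays ranged from 1641 (without double knockout 2) to 6622 (without wild type 2) for double knockout placentas, 3255 (wild type 5) to 8295 (wild type 4) for triple knockout placentas. They ranged from 1844 (Sox2Cre 2) to 5805 (wild type 1) for Sox2Cre placentas and 1954 (Cyp19Cre 3) to 2936 for Cyp19Cre against Sox2Cre placentas. In embryos they ranged from 2998 (triple knockout 5) to 6891 (triple knockout), 2447 (Sox2Cre 2) to 4923 (Sox2Cre) and 3122 (Cyp19Cre 1) to 3968 (Cyp19Cre against Sox2Cre). Counts of double knockout placentas also moved by over 1.5 times without double knockouts 1, 3 and 4 (1865, 1842, 2392) and wild types 1, 5 and 6 (6555, 2114, 2221). Those of Sox2Cre placentas did so without Sox2Cre 1, 3 and 4 (2057, 2170, 2048) and wild type 2 (5789). Those of triple knockout placentas did so without triple knockouts 1 and 2 (3525, 3540) and wild types 3 and 6 (8165, 3351), those of triple knockout embryos without triple knockout 1 (3001) and those of Cyp19Cre against Sox2Cre placentas without Cyp19Cre 2 (2291).

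Within array sets the ranges with 1 array left out were, in placentas, 681 to 1799 (double), 775 to 2148 (triple), 50 to 336 (triple against double), 101 to 632 (E2f3a) and 75 to 309 (interaction). In embryos they were 2176 to 5145, 90 to 334, 287 to 2717, 485 to 1454 and 217 to 2431 in the same order, and 1261 to 3013 for the tissue difference and 34 to 66 for Sox2Cre placenta minus embryo. The G1/S median of Cyp19Cre embryos ranged from -0.31 to -0.17 and passed without Cyp19Cre 1 (-0.18, adjusted p = 0.0385).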

Other observations

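The list of cholesterol synthesis genes and its test were chosen after the values were seen. In double knockout embryos Insig1, which restrains sterol synthesis and is itself induced by its regulators, was among the lowest genes. A list of 20 cholesterol synthesis genes was then tested within array sets, and 16 of the 17 measured were lower and none higher in double knockout embryos (median log2 change -0.79, camera p = 2.58e-19, 0.0122 with an estimated correlation). The median was 0.01 in triple knockout embryos and -0.05 in double knockout placentas, where 2 of 17 were lower. Lower expression of this pathway as a group in double knockout embryos is a hypothesis found and tested on the same arrays; these differences between genotypes and tissues were not tested for the list.

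Erythroid markers of triple knockout embryos had a median of 0.56 within array sets, with 1 of 21 higher over all genes tested and 14 adjusted over the list alone (camera adjusted p = 5.44e-13, 0.228 with an estimated correlation). Macrophage markers of E2f3a knockout embryos had 3 of 16 higher (median 0.34, adjusted p = 4.31e-05, 0.238 with an estimated correlation).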
